A study of Homo sapiens with 6 samples.

How the data were processed

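RNA was measured in SiHa, an established cell line from a cervical squamous cell carcinoma that carries human papillomavirus. Per the labels' protocols, cells were seeded in transwell plates of 6 wells, the migrated and non-migrated cells were scraped and pooled 10 hours later, and RNA was extracted with Trizol, treated with DNase and made into libraries with a TruSeq RNA kit. Each fraction had 3 libraries, numbered by replicate set. The labels do not say whether the sets came from separate cultures, so p-values measure the spread between these samples, which may be technical.

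The submitters' processing notes name CASAVA 1.8.2, TopHat2, Cufflinks 2.2.1, Cuffdiff and the genome build hg19, with no order or settings. The annotation and the strand setting of the counting are not given in the sources used here, so fragments of overlapping or antisense genes, and of near-identical copies, could not be told apart. Per the file headers, the deposited expression table is a Cuffdiff table with 1 row per locus and library. Per the file headers, its deposited estimated counts are the fragments that Cuffdiff assigned to each locus and library before scaling, and 3.31% of the nonzero values were not whole numbers. The same deposited table gives FPKM, fragments relative to locus length and library size after Cuffdiff scaled the libraries against each other. Cuffdiff marked 18 values at 14 loci as failed. The rows name the fraction and a replicate index, and the index was read as the replicate number of the labels in the same order. The fraction of each library is therefore certain, while the number within a fraction is an assumption.

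The table identifies 26006 loci by an assembly ID, and the files used here do not pair these IDs with gene names or positions. No fold change could therefore be given for SUV39H1 or any other named gene, for the gene lists or for the gene families. Only 2 IDs that rose and 2 that fell are printed. A further 2 deposited lists give gene symbols with hg19 positions, named as genes of high and of low expression. They hold no expression values, and their selection rule and the libraries behind them are not given in the sources used here. They were read as lists of expression level, not of change between the fractions, so the overlap planned between them and the calls was not made.

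The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, a robust quasi-likelihood fit and a two-sided quasi-likelihood F-test. Benjamini-Hochberg adjustment ran over 13551 tested loci, with a threshold of 0.05. Fold changes are migrated relative to non-migrated. Relative locus length was taken as the ratio of scaled fragments to FPKM, averaged over libraries. The standard error of a log2 fold change was taken as its size divided by the square root of F. The fit without a block for the replicate set was chosen before the data were examined. The series describes paired sets, and deviations from the group means were compared between same-numbered libraries across the 13551 loci. They correlated at 0.463, 0.401 and 0.329, while differently numbered libraries gave -0.299 to -0.0944. Deviations cancel out within a fraction, so the negative values follow largely from the positive ones and add little evidence. From the positive values the numbers were taken to pair the samples. The blocked value is printed beside a result where it changed a call or moved a count of calls by over 1.5 times.

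Depth was 18226280 to 33466924 assigned fragments per library. Replicates of 1 fraction differed by more than counting noise, with a chi-square per degree of freedom of 9.54 to 14.4, so no libraries were merged. The tests were tried on simulated counts for 13439 loci, with changes of 1.25, 1.5 and 2-fold planted at 67, 67 and 66 loci above 1 CPM. The simulated counts included set effects, and their spread was estimated with the replicate set in the model, which favours the fit with the block. Far fewer loci were changed than were called in the data, which makes the adjusted threshold stricter. Without the block, 13.4% of changes of 1.25-fold, 73.1% of 1.5-fold and 89.4% of 2-fold were recovered, with 0 false calls. With the block, 74.6%, 95.5% and 100% were recovered, with 9 false calls.

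Named loci were those with the largest rise and fall among loci past the threshold whose 3 migrated values all lay on one side of the 3 non-migrated values, with a mean log2 CPM of at least 1. This rule was set before the data were examined for 10 loci in each direction and was shortened because the IDs have no names. In place of the planned tests, 29 gene lists and 4 name-defined families, all written beforehand, were counted on the deposited lists. Groups with at least 5 listed members were tested for an uneven split between both lists with a two-sided Fisher's exact test (scipy 1.17.1). These 31 tests and 6 of families picked after the lists were seen were adjusted together over 37 tests. The later families had small p-values, which can lower the adjusted p of the groups written beforehand. Example genes are among the first listed members in the order written beforehand, and some lists and genes are not reported here.

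Alternatives were another scaling, other filters, DESeq2 1.42.0, limma 3.58.1 with voom, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1, unrounded values, a minimum fold of 1.5, the replicate block, and leaving out each library. For the gene lists they were matching by older and newer symbols, listed protein coding genes alone as the background, and a background without olfactory receptor, keratin associated, defensin and LINC genes.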

Results

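The transcriptomes of SiHa cells that had crossed a transwell membrane and of cells that had not were compared, with 3 libraries of each fraction. The series title names a chromatin state low in SUV39H1, a histone H3 lysine 9 methyltransferase, in migratory cervical cancer cells. The non-migrated libraries held 33466924, 20487161 and 18226280 assigned fragments, and the migrated libraries of the same sets 25662866, 23166447 and 23351986. Fragments were detected at 16932, 16427 and 16271 loci in the non-migrated fraction and at 16329, 16154 and 16198 loci in the migrated fraction. At the depth of the shallowest library, 16271 to 16318 loci would be detected in the non-migrated and 15917 to 16001 in the migrated libraries. The first principal component carried 49.9% of the variance and separated the fractions, and the next 2 components carried 19.1% and 16.6%.

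The first comparison asked which loci differed between migrated and non-migrated cells. Many loci differed by small amounts, and the larger changes were mostly losses in migrated cells. By edgeR's quasi-likelihood test, 876 loci were higher and 866 lower in the migrated fraction, of 13551 tested. Among them 31 rose and 134 fell by over 2-fold, and 74.9% of the called changes were under 1.5-fold. The 31 became 15 and 20 without non-migrated library 2 and 3, and 19 and 18 without migrated library 1 and 2. The median change was 1.27-fold for loci that rose and 1.34-fold for those that fell. The 3 values of each fraction did not overlap at 35.4% of tested loci, against 10% expected by chance for 3 against 3 unpaired libraries, a share that pairing would alter. With the replicate set as a block, 2824 loci were higher and 2690 lower, 5514 in all, of which 38 rose and 176 fell by over 2-fold. The blocked fit called 1739 of the 1742 loci in the same direction, and with scaling by library totals alone the split was 573 higher and 1226 lower.

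**Figure D1:**
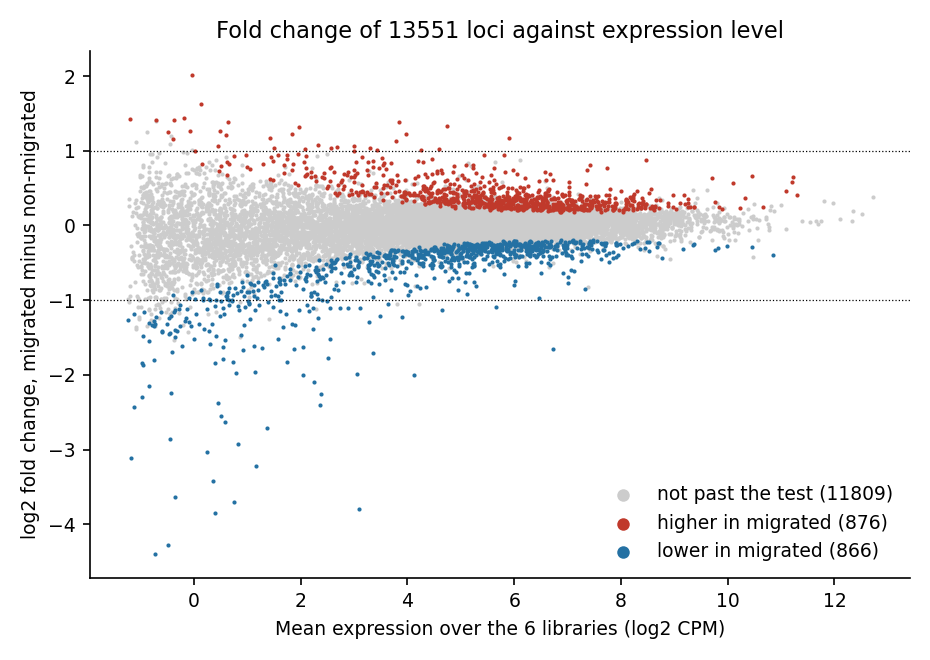
Log2 fold change of migrated against non-migrated cells for each of 13551 tested loci (vertical axis) by mean expression over the 6 libraries in log2 CPM (horizontal axis), with dotted lines at 2-fold. Red points are the 876 loci higher and blue points the 866 loci lower in the migrated fraction by edgeR's quasi-likelihood test, and the points beyond 2-fold lie mostly below the lower line.

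The locus XLOC_000513 showed the largest fall under the naming rule. Its expression was 15.9 ± 7.91 CPM (SD, n = 3) in non-migrated and 1.14 ± 0.537 CPM (SD, n = 3) in migrated cells, a log2 fold change of -3.79 (SE 0.460, edgeR adjusted p = 0.00424). XLOC_009191 fell from 3.79 ± 0.597 to 0.406 ± 0.0863 CPM (SD, n = 3 each), a log2 fold change of -3.21 (SE 0.244, edgeR adjusted p = 0.000220). XLOC_025689 rose from 7.82 ± 1.48 to 20.6 ± 2.12 CPM (SD, n = 3 each), a log2 fold change of 1.39 (SE 0.136, edgeR adjusted p = 0.000630). XLOC_010951 rose from 14.9 ± 5.55 to 38.5 ± 13.6 CPM (SD, n = 3 each), a log2 fold change of 1.34 (SE 0.321, edgeR adjusted p = 0.0364). Without the block, this call was lost when any library but the third migrated one was left out. With the block, it was kept without set 1 or set 2 and lost without set 3 (edgeR adjusted p = 0.119). The naming rule was met by 851 loci that rose and 755 that fell, and with the block by 1918 and 1694.

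With TMM scaling, weakly expressed loci were lower and strongly expressed loci slightly higher in migrated cells. The median log2 fold change was -0.17 in the lowest expression decile and 0.06 in the highest. Over all loci the median was 0.00211 with TMM and -0.0436 with library totals, so the sign of small medians depends on the scaling. Of called loci above the median expression 615 rose and 396 fell, against 261 and 470 below it, an odds ratio of 2.80 (95% interval 2.29 to 3.42). With the block these were 1970 and 1307 against 854 and 1383, an odds ratio of 2.44 (2.18 to 2.73). Both intervals treat loci as independent and do not measure the spread between libraries. Across loci, which are not independent replicates, the rank correlation of fold change with expression level was 0.206. The difference between the highest and lowest decile was 0.15, 0.28 and 0.25 on the log2 scale in the 3 replicate sets. Fold change also fell with locus length, at a rank correlation of -0.151 across loci, and of -0.221, -0.180 and 0.00585 in sets 1, 2 and 3, so the trend was absent in set 3. Of called loci in the shortest of 5 length classes 213 rose and 77 fell, against 125 and 320 in the longest, and with the block 731 and 269 against 415 and 872.

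**Figure D2:**
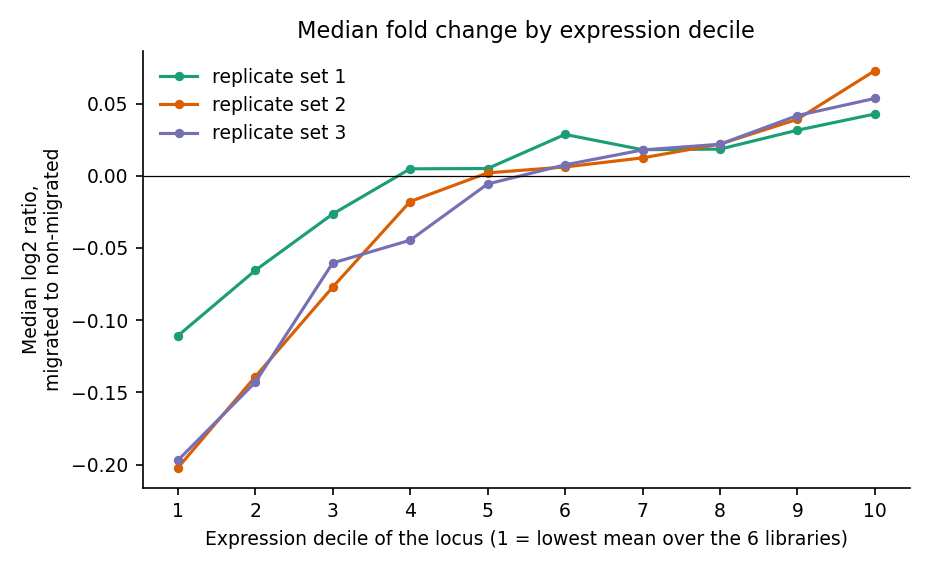
Median log2 ratio of migrated to non-migrated expression (vertical axis) in each of 10 expression deciles, from lowest to highest mean level (horizontal axis), with 1 line per replicate set. Libraries were scaled by TMM. All 3 sets start below zero, at -0.11, -0.20 and -0.20 in the lowest decile, and end above it, at 0.04, 0.07 and 0.05 in the highest.

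The second comparison asked where genes of chromatin, migration and cervical epithelium stood on the deposited lists of high and low expression, which were taken to describe level and not change between the fractions, as their selection rule is not given in the sources used here. The high list held 4531 genes and the low list 4419 symbols. Many genes of the low list are silent in most tissues, so any group of widely expressed genes is likely to lean to the high list. The tests below do not set a group apart from widely expressed genes in general. AKAP17A, CD99, PLCXD1 and SLC25A6 stood on both and were left out. Each was on the high list at a position on chromosome X and on the low list at a position on Y. SUV39H1 was on neither list, and nor were its paralog SUV39H2, the H3K9 methyltransferases SETDB1 and SETDB2, or MPHOSPH8, a component of the HUSH silencing complex. The other 11 of 16 H3K9 methyltransferases and HP1 partners were on the high list and 0 on the low list (Fisher's exact test, adjusted p = 0.00158). They included EHMT1 (hg19 chromosome 9, 140513444 to 140730576) and EHMT2 (chromosome 6, 31847536 to 31865461), which methylate H3K9 in euchromatin. They also included the HP1 genes CBX1 (chromosome 17, 46147414 to 46178883), CBX3 (chromosome 7, 26240782 to 26252976) and CBX5 (chromosome 12, 54624724 to 54673955).

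Among H3K9 demethylases, KDM1A, KDM3B, JMJD1C, KDM4A and PHF8 were on the high list and the remaining 6 of 11 on neither. With 5 listed genes, all of them high, Fisher's exact test gives p = 0.0625, the smallest such a split allows, so no lean to the high list could pass. Of 22 genes of Polycomb repression and DNA methylation, 9 were on the high list and 0 on the low list (adjusted p = 0.00603). EZH2, the H3K27 methyltransferase, and its partners EED and SUZ12 were among the 9, as were the maintenance methyltransferase DNMT1 and its cofactor UHRF1.

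Where genes of adhesion and matrix were listed, they stood mostly on the high list. Integrins, laminins and focal adhesion genes gave 20 of 30 high and 0 low (Fisher's exact test, adjusted p = 5.08e-06), including ITGA3, ITGA5 and ITGA6. Matrix proteases and inhibitors gave 14 of 27 high and 0 low (adjusted p = 0.000252), including the membrane protease MMP14 and the urokinase receptor PLAUR. Genes responsive to YAP and TAZ gave 10 of 22 high and DLC1 low (adjusted p = 0.0174), and TGF-beta responsive genes 12 of 25 high, with COL4A1 and COL4A2 low (adjusted p = 0.0185).

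Epithelial and mesenchymal identity genes were split and did not pass the test. Epithelial junction and identity genes gave 8 high, including TJP1, ESRP2 and DSP, with GRHL2 and DSC2 low (adjusted p = 0.127). Mesenchymal genes gave COL5A1, COL6A1, LOXL2, TGFBI and TNC high, with CDH2 and COL1A2 low, and 22 of 29 on neither list (adjusted p = 0.479). Squamous differentiation genes were mostly low, 19 of 33 against SLPI alone high (odds ratio 0.0511, Fisher's exact test, adjusted p = 3.90e-05). The low genes included the suprabasal keratin KRT1 and the cornified envelope proteins IVL and LOR. Basal squamous and stem-associated genes gave 7 high, including KRT17, CD44 and ALDH1A3, with KRT5, SOX2, NANOG, PROM1 and PDPN low (adjusted p = 0.796).

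The listed genes of growth and metabolism stood mostly on the high list. All 53 cytosolic ribosomal protein genes were high (Fisher's exact test, adjusted p = 1.73e-15). Mitotic genes gave 29 of 32 high and 0 low (adjusted p = 1.56e-08), including MKI67, TOP2A and CCNB1, and replication genes 27 of 31 high and 0 low (adjusted p = 5.09e-08), including PCNA, MCM2 and MCM3. Nuclear genes of oxidative phosphorylation gave 35 of 42 high and 0 low (adjusted p = 2.76e-10), and mitochondrially encoded genes 12 of 13 high and 0 low (adjusted p = 0.000824). Heat shock genes gave 17 of 21 high (adjusted p = 3.79e-05), cholesterol synthesis genes 15 of 25 (adjusted p = 0.000134) and genes of the endoplasmic reticulum stress response 12 of 25 (adjusted p = 0.000824), each with 0 low. Hypoxia and glycolysis genes gave 17 of 32 high and SLC2A3 low (adjusted p = 0.000284), and p53 responsive genes 7 of 22 high and 0 low (adjusted p = 0.0207).

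Inflammatory genes were even, with TNFAIP2, NFKBIA, NFKB1, ICAM1 and SOD2 high and CXCL5, CXCL6, IL1RL1, CSF2 and TNF low (Fisher's exact test, adjusted p = 1). The immediate early genes FOSL2, IER2, IER5, MYC and KLF10 were high and 26 of 31 on neither list, again too few listed genes for a lean to the high list to pass (Fisher's exact test, p = 0.0625). Notch pathway genes gave 6 high and HEYL low (adjusted p = 0.140). Blood cell markers, mostly of leukocytes, gave 11 of 20 low and 0 high (adjusted p = 0.000781), including PTPRC, CD3D and CD2 and the haemoglobin genes HBA2 and HBB of red cells. Endothelial markers gave KDR, TIE1 and EMCN low, and fibroblast markers FBLN1 high with COL1A2 and DPT low, too few to test.

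Zinc finger genes named ZNF, many of which encode repressors that recruit H3K9 methylation, were more often low, at 89 against 32 high (odds ratio 0.346, Fisher's exact test, adjusted p = 1.83e-07). Clustered protocadherins gave 6 low and 0 high (adjusted p = 0.0198) and long non-coding genes named LINC 126 low and 0 high (adjusted p = 1.78e-38). Histone genes gave 3 high and 7 low (adjusted p = 0.240). Counting groups not reported here, 17 of the 31 groups tested passed with more members on the high list and 5 with more on the low list. The low list held many genes silent in most tissues. No call changed against listed protein coding genes alone, or with olfactory receptor, keratin associated, defensin and LINC genes left out, in the groups that could be tested so. Both backgrounds kept other genes of the low list, so they need not remove the lean of widely expressed groups.

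**Figure D3:**
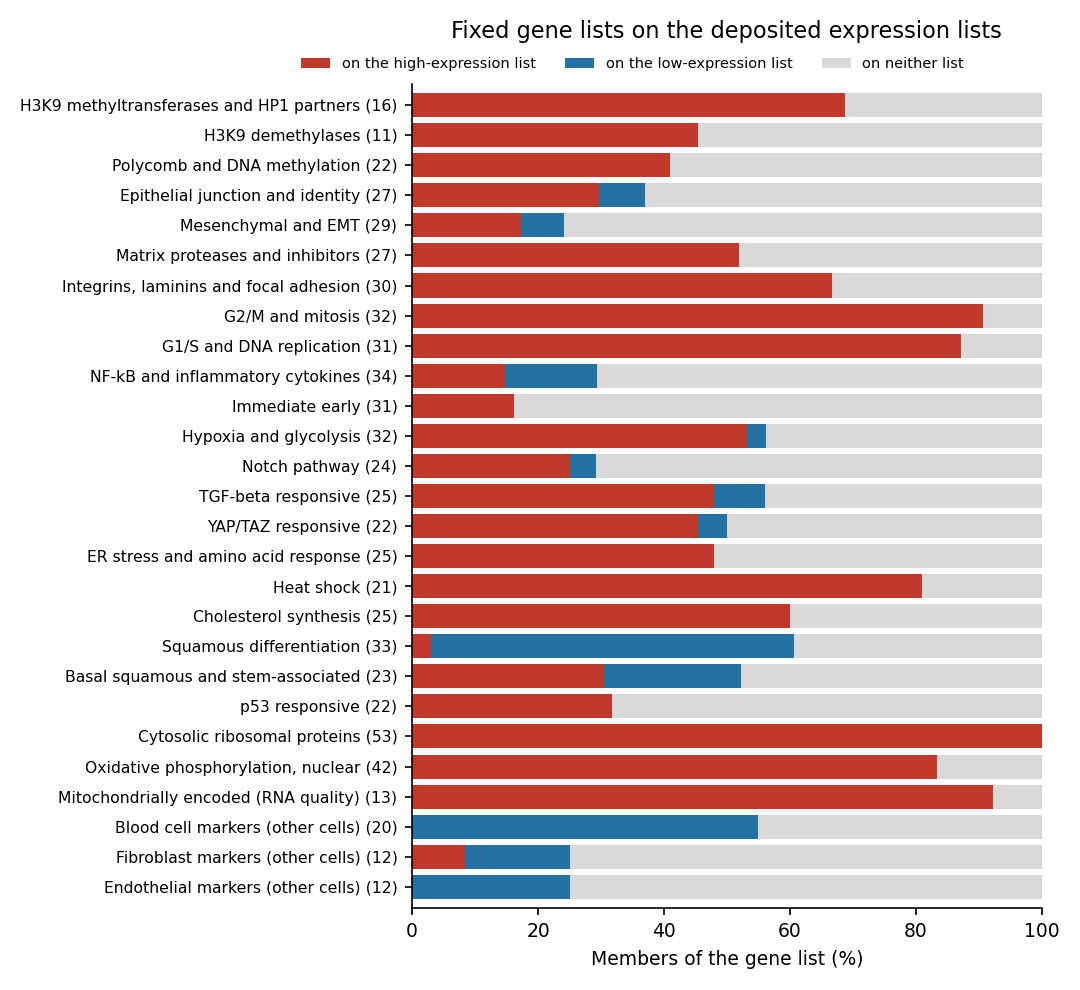
Share of the members of each gene list shown (horizontal axis, percent) that stood on the deposited high list (red), the low list (blue) or neither (grey), with the number of members in parentheses. All 53 cytosolic ribosomal protein genes are red, while squamous differentiation and blood cell markers are mainly blue or grey.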

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

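All alternatives were planned except those joining the block with another choice, the omission of failed loci, and the list alternatives, which were chosen after seeing the data. Against 1742 loci without a block, the replicate block gave 5514, which parts the paired sets from the residual spread. The block gave 2941 with DESeq2, 5513 with limma voom and 141 (43 higher, 98 lower) with a minimum fold of 1.5, and without set 1, 2 or 3 it gave 3875, 3515 and 5152. A minimum fold of 1.5 without the block left 32 (4 higher, 28 lower). Limma-trend on log2 FPKM called 90 with a pseudocount of 1, 87 with 0.1 and 28 with no filter, and the cause was not tested. Leaving out 1 library gave 707 to 1205 loci, with fewer samples in the fit. The count was 1062, 826 and 1205 without non-migrated library 1, 2 and 3, and 956, 707 and 794 without migrated library 1, 2 and 3. Loci called over 2-fold, 31 higher and 134 lower, became 15 and 46 with at least 1 CPM in every library, 4 and 12, 11 and 21, and 1 and 6 with limma-trend on FPKM (pseudocount 1, 0.1, and unfiltered), and 3 and 27 with a minimum fold of 1.5. With the block they were 38 and 176, but 21 and 82 with a minimum fold of 1.5, 46 and 212 without set 1 and 51 and 208 without set 3.

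Other scalings, filters and tools without the block gave 1560 to 1924 loci, and unrounded values and the omission of failed loci each gave 1742. The share of called loci that were higher was 50.3%, but 31.9% with library totals, 32.1% with unfiltered FPKM, and 12.5% and 30.5% with a minimum fold of 1.5 without and with the block. The rank correlation of fold change with level stayed positive in every alternative run, at 0.142 to 0.236. No named locus changed direction, and the block alone ended none of their calls. Among the alternatives that tested each, XLOC_025689 and XLOC_000513 lost their call only with unfiltered FPKM, XLOC_009191 in none, and XLOC_010951 in 12 of 26, where its adjusted p was 0.0527 to 0.858. No list or family written beforehand changed its call with other symbols, a protein coding background or one without olfactory receptor, keratin associated, defensin and LINC genes, where these gave it a value, and the later families were not run under them.

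The planned results for SUV39H1, the gene lists and the families as fold changes, and the overlap of calls with the deposited lists, were not run, since the table's IDs have no gene names. Without the block, 13.4% of the smallest simulated changes were recovered, so small changes missed there are not shown to be absent.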

Other observations

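The families and chromosomes described first, the patterns weighed after them, the tests of library bias and of the agreement of window profiles between sets, and the use of bootstrap spreads to judge the tests were all chosen after the data had been seen. The other tests were fixed after these patterns were noticed, but before their own values were computed.

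Further gene families stood almost wholly on 1 of the deposited lists. They were picked after these lists were seen, so their p-values describe the split and do not test it independently. Olfactory receptor genes gave 367 low and 0 high (Fisher's exact test, adjusted p = 3.90e-115), keratin associated protein genes 89 low and 0 high (adjusted p = 4.12e-27) and beta defensins 37 low and 0 high (adjusted p = 2.61e-11). Cancer-testis genes of the MAGE, GAGE, SSX and XAGE families gave 66 low and 2 high (adjusted p = 2.98e-17). Mitochondrial ribosomal protein genes gave 35 high and 0 low (adjusted p = 2.76e-10) and proteasome subunit genes 36 high and 2 low (adjusted p = 2.04e-08).

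Listed protein coding genes were also compared between chromosomes. Olfactory receptor, keratin associated and beta defensin genes were left out, as were the MAGE, GAGE, SSX and XAGE cancer-testis genes. Chromosome Y and the mitochondrial chromosome were not tested, but any listed protein coding genes on them stayed among the genes compared with each other chromosome. The share on the high list differed between chromosomes. It was 36.4% on X, 37.4% on 4 and 41.4% on 13, against 76.6% on 16 and 73.7% on 15 (Fisher's exact test of each against the rest, adjusted over 23 tests, p = 7.49e-16, 4.35e-12, 0.000371, 1.33e-12 and 7.15e-06). No explanation of these shares was tested.

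The real division into migrated and non-migrated libraries gave 1742 loci, and the highest of the other splits gave 0. There are 10 splits of 6 libraries into 3 and 3, of which 1 gave as many, too few for a share under 0.05. Of the 4 splits that part every pair, the real one gave 5514 with the block and the highest other 0. These 4 are also too few for a share under 0.05. All other splits mix the fractions, so a difference between the fractions adds to their residual spread and few calls were likely.

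The lower level of weakly expressed loci in migrated cells was set against 3 technical explanations. Unequal depth was argued against as the whole cause. After thinning to one depth, the smallest gap between highest and lowest decile was 0.17 on the log2 scale (95% bootstrap interval 0.11 to 0.22). This gap was 0.17, 0.27 and 0.25 in sets 1, 2 and 3, so its sign held in each. Locus length was also argued against as the whole cause. The smallest rank correlation with level within 5 length classes was 0.152 (0.113 to 0.196). The bootstrap intervals in this paragraph treat loci as independent and do not measure the spread between libraries. As neighbouring loci correlate, these intervals are likely too narrow. Evenly spread background, such as genomic DNA in the non-migrated libraries, stayed open: longer loci in the lowest 3 deciles fell slightly more, at a rank correlation of -0.0955 (-0.125 to -0.0669), near the -0.1 it would need. By set this was -0.116, -0.0729 and -0.0427, strongest in set 1, where the gap between deciles was smallest. That order runs against background but rests on 3 sets and was not tested. Over all loci the rank correlation with length was -0.151, and -0.221, -0.180 and 0.00585 by set, stronger than in these deciles except in set 3. The bound of -0.1 therefore cannot tell background from the general trend with length. A loss of low-level transcription in migrating cells may also account for the pattern and cannot be told apart from such background with these data.

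Fold changes of loci with consecutive ID numbers were correlated, at 0.135 over 8508 pairs. Medians over 125 windows of 200 IDs ran from -0.20 to 0.17 and correlated at 0.894 to 0.924 between the replicate sets. The windows used only loci with a mean log2 CPM above 3, at least 20 in each, so they do not cover weakly expressed loci. The bootstrap intervals in this paragraph treat loci or windows as independent, which the correlation of neighbours contradicts. These intervals are therefore likely too narrow, and they do not measure the spread between libraries. Shared level and length were argued against as the whole cause, since the correlation was 0.154 after regression on both (highest of 1000 shuffles 0.0356), and so were fragments shared between adjoining loci, since loci 5 IDs apart still correlated at 0.0862 (highest shuffle 0.0403). Covariation that differs from set to set was argued against as the source of the window profile. Sets that share no library correlated at no less than 0.894 (0.852 to 0.922, highest circularly shifted profile 0.512). Any difference between the fractions that recurs in every set, also a technical one, would give this agreement, so it does not tie the profile to migration. For the lag correlation, covariation unrelated to migration stayed open. There, contrasts between sets reached 0.0865 (covariance at most 0.00458, against 0.0144 for the fractions). The difference of 0.0487 exceeded the margin of 0.03 set for it, while the lower end of its interval (0.0183 to 0.0819) did not. A library bias that also varies between sets stayed open as well, as the window profiles of set contrasts correlated with that of the fractions at up to 0.296 (0.146 to 0.472), under the bound of 0.3 by value alone, so that the use of intervals left both open. If the IDs follow genome order, which the sources used here do not state, regional chromatin, base composition or copy number differences between the fractions could each give such runs, and none was tested.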
